A study of Homo sapiens with 8 samples.

How the data were processed

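The data are 8 libraries of MOLM-13 cells in 4 groups of 2: footprints and input RNA with the control hairpin or the circMYBL2 hairpin. Groups come from the sample titles. Per the labels' protocols, all libraries were made with a ribosomal RNA removal kit and a small RNA library kit. The authors used cutadapt, Bowtie, HISAT2, featureCounts and DESeq2 with build hg38, per their processing notes. Versions, roles and order are not given in the sources used here. Nor is the strand setting, so reads of overlapping and antisense genes are not separated with certainty. The deposited footprint table holds RPKM values made by the authors, which are reads scaled to gene length and to a total for each library that is described below. The deposited input RNA table holds FPKM values made by the authors, in the same manner. Both list the same 58302 genes with Ensembl identifiers, symbols and biotypes, of which 30194 were above 0 in a library. Coordinates of 3 genes were taken from a RefSeq table of GRCh38.p14, the same build as hg38. All value columns were used. The 2 footprint columns of sh-circMYBL2 name the group but not the replicate.

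Neither table gives counts. In both, a value times the gene's length was a whole multiple of a fixed step in each library, so the read number behind each value was recovered within a tolerance of 0.02 reads for all but 4 genes. For microRNA genes, 98.2% to 99.1% of the values above 0 came out whole on their own. The step also gave the total each library was scaled to. This total matched a median-ratio size factor times the geometric mean of the totals (file over computed value of 1.00068 for footprints and 1.00087 to 1.00101 for RNA), so the tables had been scaled in this way before deposit. Read recovery was tested on simulated values: 93.1% of 3228 genes were exact in every library, and 99.9% of reads were recovered. Recovered reads gave depths, composition, counting intervals (Wilson for shares, Poisson for single genes, 95%) and a floor of 3 reads for a group at 0. A scaled ratio to this floor, called a bound below, takes the reads of the other group as exact. It leaves out their counting error and the spread between replicates. They did not enter the main tests. The scaling totals are not the reads on genes: sh-NC footprint library 2 had 300379 reads and a scaling total of 185632. The shallowest footprint library had 80156 reads, so that 1 read is a large step there; the floor of 3 reads was 36.5 RPM of the scaling total in sh-NC library 1 and 2.69 RPM in sh-circMYBL2 library b.

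Tests were fixed before the data were examined, on the assumption that the tables held RPKM and FPKM or counts; they held the former. Each table was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) on log2(value + 1), for genes with a mean of at least 1 over the 4 libraries. TE was the interaction of hairpin and assay in a fit of all 8 libraries over genes passing that filter in both tables. That fit gave each gene a single variance over both assays, although footprints varied far more than RNA. RNA libraries thus added degrees of freedom (5.75 in TE against 4.16 in footprints) to a spread that came mostly from footprints. TE p-values and intervals may therefore be too optimistic. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Log2 changes and their SE are on the log2(value + 1) scale, which understates changes of low genes. Exact permutation of 2 against 2 libraries cannot give a p under 0.333, so the moderated test of limma was used throughout.

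Gene lists were fixed before the data were examined, 34 in all, including markers of erythroid, megakaryocyte, lymphoid and adherent cells. Lists with at least 5 tested members were tested with camera (preset correlation 0.01) and adjusted over the lists of a comparison. Camera with an estimated correlation and fry stand beside it. With an estimated correlation camera uses the few residual degrees of freedom of the fit, so few lists could pass whatever their correlation. Named genes followed a rule fixed in advance: FLT3, MYBL2 and PTBP1; up to 12 protein-coding genes per comparison and direction with the largest change among those past the threshold, with a mean of at least 5 and no overlap between the groups; up to 5 by smallest p where fewer than 5 passed; and up to 4 members of each described list. Since footprint columns carry no replicate number, no overlap in TE was asked of every pairing of footprint and RNA libraries. HIST1H2AB to HIGD2A, HDLBP, CCT7, LMNB1, CAMK1 and AP1S1 in the footprint comparison were filled in by smallest p. QARS, ACTA2, SNORA5C, MIR425, MT-ND6, IGKC, IL2RA and POLR1B fall outside the rule and were chosen after their values were seen.

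The fits were tested on simulated libraries drawn at the real means and depths with genes changed by known folds. Dispersions estimated from the libraries were 0.00114 for RNA and 0.0963 for footprints. In 10 sets drawn with no change, at most 30 footprint genes were called higher and 1 lower, at most 21 TE genes higher and 1 lower, and no RNA gene either way. A list of 30 genes shifted by 0.5 was found in RNA (adjusted p = 1.04e-30) but not in footprints (adjusted p = 0.764) or TE (adjusted p = 0.138).

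Alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 5, median-ratio scaling, quantile normalization, eBayes without a trend or robust, protein-coding genes only, genes above 0 in every library, an adjusted p under 0.1, all 8 libraries in 1 fit, the replicate number as a block (RNA), and each library left out in turn. Voom on recovered reads, a filter of 10 recovered reads, median-ratio scaling on protein-coding genes and footprint libraries thinned to the same scaling total were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.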

Results

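The series measured ribosome footprints and input RNA in MOLM-13, an established acute myeloid leukaemia line that carries an MLL-AF9 fusion and an internal tandem duplication in FLT3. Cells carried either a control hairpin (sh-NC) or a hairpin against circMYBL2, a circular RNA made from the MYBL2 gene (sh-circMYBL2). There were 8 libraries in 4 groups. Each hairpin had 2 footprint and 2 input RNA libraries. The series title asks whether circMYBL2 regulates translation of FLT3. The hairpins were compared in 3 ways: the level of input RNA, the level of footprints, and the change in footprints beyond that in RNA, called translational efficiency (TE). The deposited tables list genes, and circMYBL2 was not matched to any row, so no value of it is given. The labels do not say that libraries of a group came from separate cultures. P-values of single genes thus measure only the spread between these samples, which may be technical. Camera p-values of lists at the preset correlation set genes against genes. They do not measure the spread between libraries, however small they are.

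The input RNA libraries held 13504020 to 14602543 reads on genes. The footprint libraries were far shallower and uneven: 80156 reads in sh-NC library 1, 300379 in sh-NC library 2, and 222845 and 715053 in the sh-circMYBL2 libraries, called a and b because the column names do not tell which replicate each is. MicroRNA genes took 42.7% and 57.2% of footprint reads with sh-NC but 32.8% and 12.2% with sh-circMYBL2, with 95% Wilson intervals of at most ±0.342 percentage points that cover counting error only. MIR425 alone held 24.8% and 37.9% of the reads of the sh-NC libraries and 15.2% and 6.18% of the others. This left 33708 and 88701 protein-coding reads with sh-NC against 125761 and 584183 with sh-circMYBL2, and 889, 2669, 3625 and 7573 protein-coding genes with at least 10 footprint reads. Libraries of the same hairpin correlated with r of 0.575 (sh-NC) and 0.804 (sh-circMYBL2) across genes for footprints, and of 0.983 for input RNA with either hairpin. Footprint libraries of different hairpins correlated with r of 0.614 to 0.700, so the 2 sh-NC libraries were less alike than either was to a sh-circMYBL2 library.

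**Figure D1:**
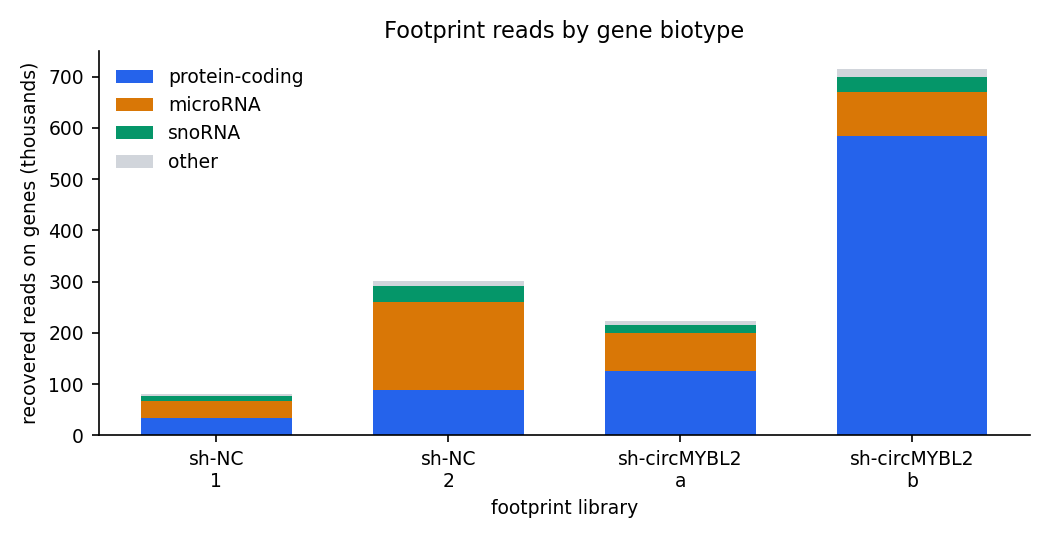
Reads recovered on genes in each of the 4 footprint libraries (y axis), stacked by gene biotype. Protein-coding genes held 33708 and 88701 reads in the sh-NC libraries and 125761 and 584183 in the sh-circMYBL2 libraries.

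The first question concerned FLT3, the receptor tyrosine kinase named in the series title, MYBL2, the host gene of the circle, and PTBP1, an RNA-binding protein. PTBP1 was chosen when the tests were planned because prior knowledge of the study tied it to circMYBL2. FLT3 (ENSG00000122025, chromosome 13, 28003274 to 28100576 in GRCh38) had 105 ± 4.48 FPKM of input RNA with sh-NC and 139 ± 3.63 with sh-circMYBL2 (mean ± SD, n = 2 each). This was a rise of 0.40 on the log2 scale (SE 0.04, 95% interval 0.27 to 0.52, adjusted p = 0.0232). FLT3 footprints were 76.0 RPKM (26 reads) and 86.8 RPKM (67 reads) with sh-NC, and 80.8 RPKM (87 reads) and 103.01 RPKM (477 reads) with sh-circMYBL2. That change was 0.17 (SE 0.36, 95% interval -0.83 to 1.16, adjusted p = 0.862). The TE change of FLT3 was -0.23 (SE 0.29, 95% interval -0.96 to 0.49, adjusted p = 0.727). Neither differed from 0 by more than the spread between replicates. Both lay below the median change over all genes tested, which was 0.56 in footprints and 0.57 in TE. Among genes above 0 in every library, as FLT3 was, those medians were -0.01 and 0.03, values that the footprint scaling holds near 0. FLT3 was not tested against either reference. Each FLT3 value covers the whole gene and does not separate the allele with the duplication from the other.

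RNA of MYBL2 (ENSG00000101057, chromosome 20, 43667114 to 43716482), a cell cycle transcription factor, rose from 1.31 ± 0.220 to 3.62 ± 0.136 FPKM (n = 2 each), which is 1.01 on the log2 scale (SE 0.10, adjusted p = 0.0209). Over the alternatives this change ran from 0.45 (pseudocount of 5) to 1.48 (voom). The value covers all exonic reads of the gene and does not check the loss of the circle. MYBL2 footprints differed by 0.13 (SE 0.68, adjusted p = 0.945), from -0.71 without sh-NC footprint library 1 to 0.96 without library 2, and its TE by -0.88 (SE 0.76, adjusted p = 0.614; -1.74 and adjusted p = 0.244 by voom). PTBP1 (ENSG00000011304, chromosome 19, 797452 to 812312) had 22.0 ± 0.105 and 25.8 ± 2.45 FPKM, a difference of 0.21 (SE 0.07, adjusted p = 0.151). PTBP1 footprints were lower in both sh-circMYBL2 libraries (55.6 and 45.1 RPKM) than in both sh-NC libraries (67.1 and 69.7 RPKM). The change was -0.44 (SE 0.36, adjusted p = 0.640) with a TE change of -0.66 (SE 0.29, adjusted p = 0.290). The footprint and TE changes of MYBL2 and PTBP1 also lay below the medians over all genes (0.56 and 0.57). Against genes above 0 in every library (-0.01 and 0.03), the footprint change of MYBL2 lay above and the others below. The RNA calls of FLT3 and MYBL2 were lost with any 1 of the 4 RNA libraries left out (adjusted p from 0.0862 to 0.128 and from 0.0786 to 0.128). Under quantile normalization the TE change of FLT3 turned to 0.16 and its footprint change was 0.80 (adjusted p = 0.687). Its footprint change turned to -0.01 without sh-circMYBL2 library b. The TE change of MYBL2 was -1.71 (adjusted p = 0.00416) without sh-NC footprint library 1 and -0.0455 without library 2.

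**Figure D2:**
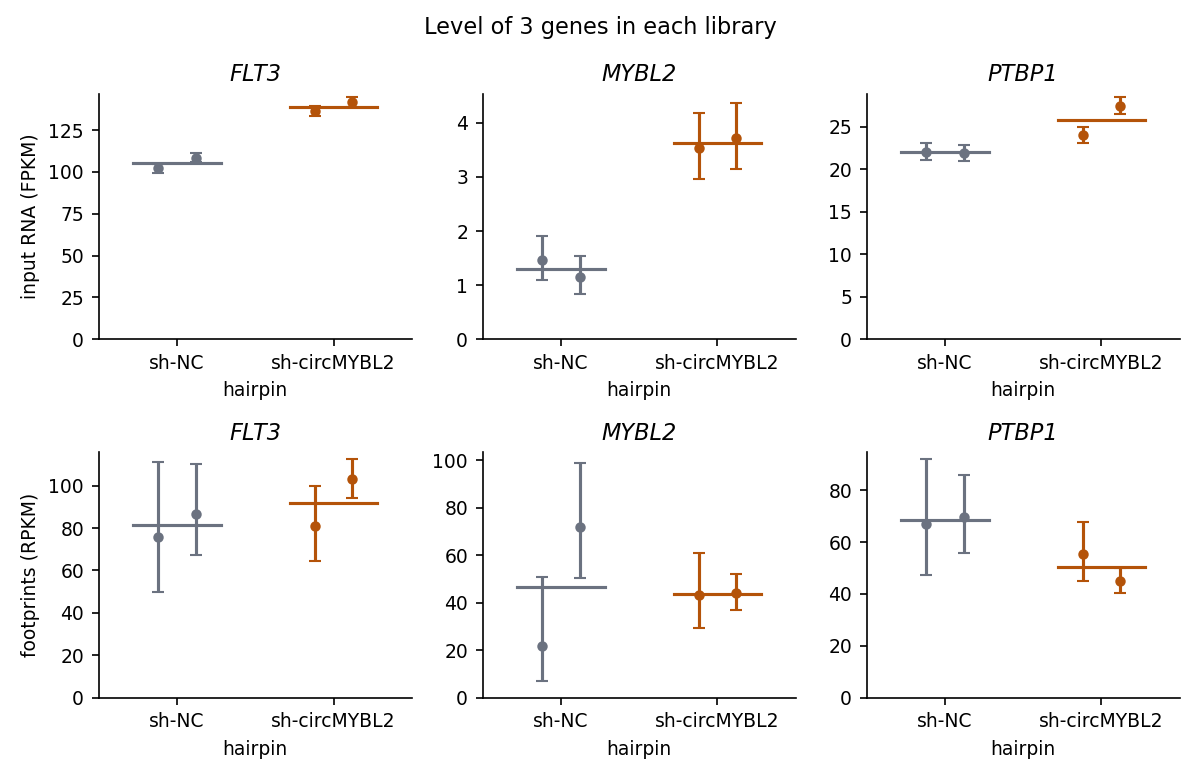
Level of FLT3, MYBL2 and PTBP1 in each library, as FPKM of input RNA (top) and RPKM of footprints (bottom), by hairpin. Points are libraries with 95% Poisson counting intervals of their reads and horizontal lines are means of 2 libraries. The mean of FLT3 RNA was 105 FPKM with sh-NC and 139 FPKM with sh-circMYBL2.

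In input RNA, genes of the cell cycle were higher with sh-circMYBL2. Of 28 DNA replication genes tested, 25 rose and none fell, with a median log2 change of 0.87. MCM4, a subunit of the replicative helicase, went from 9.77 ± 0.190 to 31.0 ± 0.151 FPKM (1.57 on the log2 scale, SE 0.04, adjusted p = 0.00720). TYMS, which makes thymidylate, went from 18.3 ± 0.419 to 50.2 ± 2.35 FPKM, and RRM2, the small subunit of ribonucleotide reductase, from 1.39 ± 0.0474 to 5.53 ± 0.101 FPKM (n = 2 each). Of 27 genes of the G2 and M phases, 15 rose and none fell (median 0.65), among them MKI67 (4.37 ± 0.0279 to 9.07 ± 0.407 FPKM) and TOP2A (5.10 ± 0.514 to 12.2 ± 0.550 FPKM). Of 52 replication-dependent histone genes, whose mRNAs are made in S phase, 30 rose and none fell (median 0.64). Those with the smallest p-values were HIST1H2BD (96.5 ± 0.211 to 168 ± 0.0343 FPKM), HIST1H2BO, HIST1H2AJ and HIST1H2AL. Histone genes have near-identical copies, so reads of single members may be split among them.

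Adjusted over the list alone, 28 of the DNA replication genes, 25 of the G2 and M genes and 44 of the histone genes passed. Set against the other genes, the 3 lists were called higher (camera adjusted p = 5.25e-22, 4.47e-15 and 4.57e-22), but each had adjusted p = 0.0862 with an estimated correlation. The correlations estimated within them were -0.034, -0.005 and -0.013, below the preset 0.01. The loss thus came with the fewer degrees of freedom of that setting and not with correlation. With any 1 of the 4 RNA libraries left out the 3 lists were called again. Their medians then ran from 0.86 to 0.94 for DNA replication, 0.65 to 0.70 for G2 and M and 0.61 to 0.65 for histones. The pseudocount moved them more: with 5 in place of 1 the medians were 0.51, 0.28 and 0.47, and with 0.1 they were 1.01, 0.85 and 0.75.

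RNAs of the amino acid and integrated stress response, the programme that ATF4 drives, were lower with sh-circMYBL2. Of 25 genes tested, 19 fell and none rose, with a median of -0.69. TRIB3, a pseudokinase induced by ATF4, went from 11.0 ± 0.196 to 2.14 ± 0.207 FPKM (-1.94, SE 0.07, adjusted p = 0.00720). ATF5 went from 30.8 ± 0.466 to 12.2 ± 0.473 FPKM, DDIT4 from 39.3 ± 1.59 to 16.7 ± 0.434 FPKM, and SLC7A11, the cystine transporter, from 11.4 ± 0.0314 to 4.54 ± 0.258 FPKM. DDIT3, which encodes CHOP, fell from 10.4 ± 0.0129 to 3.23 ± 0.575 FPKM. Of 20 aminoacyl-tRNA synthetases, 10 fell, among them WARS (36.2 ± 1.74 to 19.2 ± 0.0328 FPKM) and AARS (39.6 ± 0.388 to 24.8 ± 0.113 FPKM), and QARS rose (0.42). Of 22 genes of the unfolded protein response, 5 fell, among them HSPA5 (115 ± 0.322 to 74.1 ± 3.28 FPKM, -0.63) and SEL1L (-0.64). Of 23 p53 targets, 7 fell, among them GADD45A (25.3 ± 0.740 to 13.8 ± 0.440 FPKM) and CDKN1A (23.3 ± 0.827 to 17.3 ± 0.609 FPKM). GADD45A is also induced by stress without p53.

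The counts adjusted over the list alone were 23 lower for the integrated stress response, 13 lower and 4 higher for the synthetases, 8 lower for the unfolded protein response, and 11 lower and 1 higher for p53 targets. All 4 lists were called lower by camera (adjusted p = 2.46e-18, 0.000144, 0.00146 and 0.000663), and none with an estimated correlation (adjusted p = 0.0862, 0.443, 0.253 and 0.253 with an estimated correlation). Of the correlations estimated within the 4 lists, only that of the synthetases (0.141) lay above the preset 0.01.

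Of the 13 mRNAs encoded in mitochondrial DNA, 12 fell with sh-circMYBL2 and MT-ND6 did not pass. MT-ND3 fell from 2717 ± 159 to 861 ± 82.9 FPKM, MT-ND5 from 3784 ± 82.9 to 1251 ± 77.8 FPKM, MT-CO3 from 3047 ± 134 to 1082 ± 9.35 FPKM and MT-ND4 from 4896 ± 57.1 to 1871 ± 16.3 FPKM (n = 2 each). The 13 mRNAs held 7.49% and 7.30% of protein-coding reads with sh-NC and 4.62% and 4.39% with sh-circMYBL2. The median log2 change was -1.30, 12 were lower adjusted over the list alone, and camera gave adjusted p = 2.39e-11, but adjusted p = 0.426 with an estimated correlation. Of 45 nuclear genes of oxidative phosphorylation, 5 rose by small amounts (median 0.12), such as UQCRC1 (18.7 ± 0.364 to 26.9 ± 0.944 FPKM). So did 4 of 18 glycolysis genes (median 0.14), such as GAPDH (52.2 ± 1.99 to 71.2 ± 0.589 FPKM), while the glucose transporter SLC2A3 fell. Adjusted over the list alone 5 and 8 were higher and, for glycolysis, 1 was lower; camera gave adjusted p = 0.000611 and 0.0116, and both calls were lost (adjusted p = 0.253 and 0.443 with an estimated correlation). Glycolysis was not called by fry either (adjusted p = 0.0714).

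Single genes with large changes included CA2, which encodes carbonic anhydrase 2 and fell from 109 ± 0.709 to 21.8 ± 0.483 FPKM (-2.27, SE 0.03, adjusted p = 0.00200), ORM1, an acute-phase protein (22.1 ± 2.11 to 4.997 ± 0.283 FPKM), and FCER2, a low-affinity IgE receptor (9.52 ± 0.196 to 3.22 ± 0.0212 FPKM). ENPP2, which encodes autotaxin, rose from 17.6 ± 0.271 to 47.0 ± 1.31 FPKM, and 2 genes of macrophages and monocytes, MPEG1 (5.12 ± 0.0831 to 15.04 ± 0.266 FPKM) and MS4A6A (4.81 ± 0.411 to 13.98 ± 0.613 FPKM), rose too. CLSPN, CDC6, MND1 and HIST1H3J were also among the 12 largest rises that the naming rule picked, by 1.27 to 1.43 on the log2 scale. Of the listed markers of other cell types, none of the 19 erythroid or 12 megakaryocyte genes reached the filter, neither of 2 lymphoid genes tested passed, and of 2 genes of adherent cells tested ACTA2 was lower (-0.36). Outside these lists, 2 genes also used by lymphoid cells rose, the immunoglobulin light-chain gene IGKC (5.51 ± 0.475 to 16.3 ± 0.815 FPKM, adjusted p = 0.00972) and IL2RA (1.40, adjusted p = 0.0117).

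Over all, 12489 genes were tested in input RNA, and limma called 615 higher and 494 lower with sh-circMYBL2 at an adjusted p under 0.05. A change of at least 2-fold with no overlap between the groups was seen for 99 higher and 96 lower genes, against 43 and 39, and 28 and 33, in the 2 other ways to split the 4 libraries, where chance leaves 33.3% of genes without overlap. Of the 29 lists with at least 5 tested members, 5 were called higher and 5 lower by camera, and 0 with an estimated correlation. The other 19 had adjusted p of 0.0631 or more. No gene was called with any 1 of the 4 libraries left out (2610 to 2828 genes at an unadjusted p under 0.05, against 3653 with all) or with the replicate number as a block (0, with 3373 at an unadjusted p under 0.05). In contrast, voom on recovered reads called 1697 and 1559. On simulated RNA libraries of these depths, 37.9% of 1.5-fold, 69.7% of 2-fold and 85% of 4-fold changes among 12473 genes were called, with 12 false calls.

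**Figure D3:**
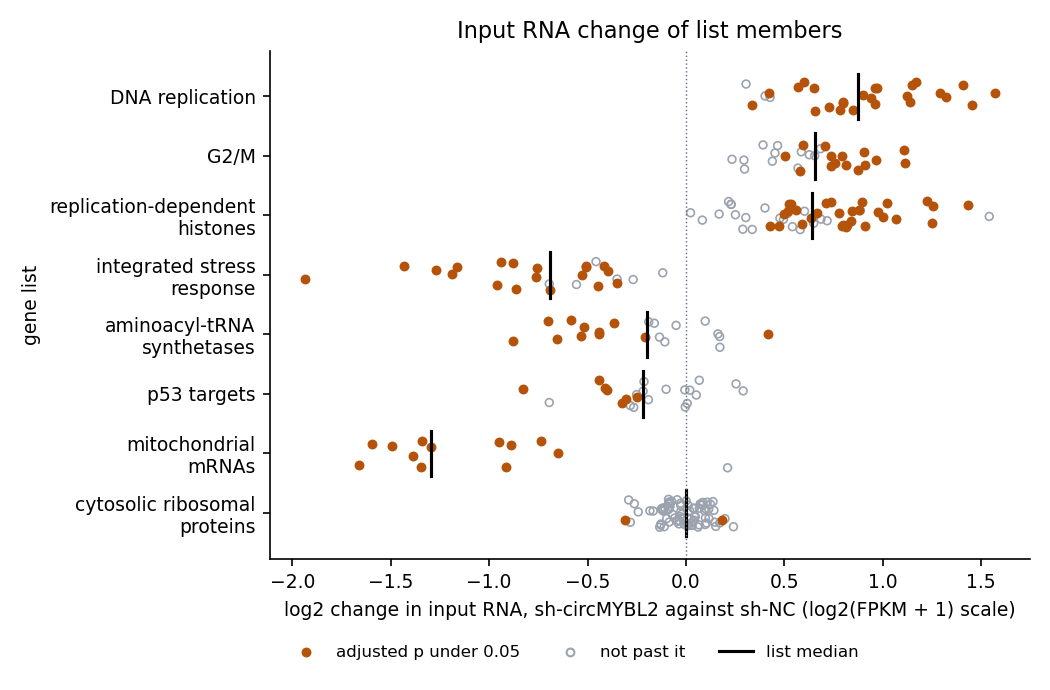
Log2 change in input RNA (x axis, log2(FPKM + 1) scale, sh-circMYBL2 against sh-NC) of each tested member of 8 gene lists (y axis). Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians; DNA replication lay at a median of 0.87, the integrated stress response at -0.69, mitochondrial mRNAs at -1.30 and cytosolic ribosomal proteins at 0.00.

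In the footprints, limma called no gene between the hairpins, while voom on recovered reads called 6 higher and 50 lower. HDLBP, an RNA-binding protein, had 369 and 272 RPKM with sh-NC and 47.2 and 31.8 RPKM with sh-circMYBL2 (985 against 580 reads in all, -3.00 on the log2 scale, SE 0.41, adjusted p = 0.323). Scaled read ratios were 0.115 for HDLBP (95% counting interval 0.104 to 0.127), 0.157 for CCT7, a subunit of the chaperonin TRiC (0.138 to 0.178), and 0.238 for LMNB1, which encodes lamin B1 (0.207 to 0.274). CAMK1 (-3.64) and AP1S1 (-2.32) were lower on fewer reads (30 against 10 and 21 against 24, adjusted p = 0.323 each). Among the smallest p-values of higher genes, HIST1H2AB, HIST1H4K, HIST2H2AB, TIMM23 and HIGD2A had no footprint read in either sh-NC library. They had 56, 22, 25, 46 and 27 reads with sh-circMYBL2 (all adjusted p = 0.323). Scaled, this is 3.64, 1.43, 1.63, 2.99 and 1.76 times a floor of 3 reads over the sh-NC group. These ratios leave out the counting error of the sh-circMYBL2 reads. None of these genes passed in limma. By voom HDLBP, CCT7 and LMNB1 were lower (adjusted p = 1.59e-05, 0.00127 and 0.0259).

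The median footprint change of the 9431 genes tested was 0.56, so list changes are given against it. It was 0.07 after quantile normalization, -0.01 among genes above 0 in every library, and 1.03 and 0.24 with pseudocounts of 0.1 and 5. Without sh-NC library 1 it was 0.24 and without sh-NC library 2 it was 1.10. Footprints of the 13 mitochondrial mRNAs had a median of -0.69, with MT-CO1 at 276 and 311 RPKM with sh-NC and 160 and 114 RPKM with sh-circMYBL2, but the median was 0.23 after quantile normalization. It was -1.18 without sh-circMYBL2 library a and -0.39 without library b, and the call was lost without sh-NC library 2 (-0.90, adjusted p = 0.181). The 75 cytosolic ribosomal protein genes had a median of 0.04 (-0.01 with RPS27 at its bound, and 0.19 after quantile normalization) with a mean of 0.13, and the 30 MYC and nucleolar genes a median of 0.00 with a mean of -0.08. Members of the latter list went both ways, 15 of 30 above 0, with FBL, the box C/D snoRNP methyltransferase, at 134 and 146 against 76.4 and 58.7 RPKM (-1.05) and POLR1B at 1.96. Camera called these 3 lists lower than the other genes (adjusted p = 0.000414, 0.0431 and 0.0225), with adjusted p = 0.996 with an estimated correlation for each, and no member passed over all genes or adjusted over the list alone. The MYC and nucleolar call held only without sh-circMYBL2 library b, and was lost without library a (0.01), sh-NC library 1 (-0.28) or sh-NC library 2 (-0.01). The ribosomal protein call was lost without library a (0.12) or sh-NC library 1 (0.04), and the median was 0.00 without library b and -0.32 without sh-NC library 2. None of the 3 was called after quantile normalization (adjusted p from 0.543 to 0.858). The cell cycle lists were not called: DNA replication footprints had a median of 0.45 (adjusted p = 0.924) and G2 and M footprints one of 0.79 (adjusted p = 0.813).

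By limma, 0 of 9431 genes passed, with 1212 at an unadjusted p under 0.05 (1047 higher and 165 lower) and a lowest adjusted p of 0.323. By size alone, 2318 genes were at least 2-fold higher and 580 at least 2-fold lower without overlap, against 538 and 1255, and 971 and 634, in the other splits. The balance turned to 1224 higher and 1429 lower after quantile normalization, and to 437 and 523 among genes above 0 in every library. Both settings hold the median near 0. Calls appeared with sh-circMYBL2 library a left out (742 higher and 4 lower) or library b left out (710 and 2), and with either sh-NC library left out limma called 0 (2038 and 3580 at an unadjusted p under 0.05). On simulated footprint libraries of these depths and a single dispersion, 0 of 61 changes of 1.5-fold, 0 of 62 of 2-fold and 1 of 60 of 4-fold were called. There were 19 false calls among the 9556 genes. Most changes of such size were not detectable in that setting, which had fewer genes at 0 than the data.

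TE asks whether footprints changed more or less than RNA. Of 11 protein-coding genes that had lower TE and a level of at least 5 in both tables, HDLBP (-3.04, SE 0.39, adjusted p = 0.0247), CCT7 (-2.45, SE 0.42, adjusted p = 0.0367) and LMNB1 (-2.06, SE 0.31, adjusted p = 0.0303) were covered by 985, 574 and 367 sh-NC footprint reads. In footprints alone the SEs of the 3 genes were larger (0.41, 0.44 and 0.37), with limma adjusted p = 0.323 for each. The TE p-values share a variance with the RNA libraries and may be too small. Their RNA was 18.3 ± 0.523 and 18.9 ± 0.807 FPKM for HDLBP, 37.3 ± 0.542 and 38.2 ± 0.835 FPKM for CCT7, and 68.8 ± 3.20 and 77.2 ± 3.65 FPKM for LMNB1 (sh-NC and sh-circMYBL2, n = 2 each). The others were SF3A2 (-2.55), FAM50A (-2.33), GALM (-2.15), SCPEP1 (-2.01), RPL37A (-1.91), PDLIM1 (-1.72), APLP2 (-1.65, on 380 sh-NC reads, but adjusted p = 0.123 by voom) and HIST1H1B (-1.57). For HIST1H1B, RNA went from 65.3 ± 0.336 to 158 ± 19.7 FPKM and footprints were 625 and 657 against 533 and 492 RPKM. CCT7, HDLBP, LMNB1, SF3A2 and the small nucleolar RNA gene SNORA5C were called lower by voom on recovered reads as well, 5 of its 12 lower calls. SNORA5C is not translated, so TE has no meaning for it. Small nucleolar RNA reads per protein-coding read were 3.30 times as high in the sh-NC footprint libraries.

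The genes with higher TE had few footprints. Of 417, 396 had no footprint read in either sh-NC library, and none had 50 or more there, with a median of 25 reads with sh-circMYBL2. Among the protein-coding genes with the largest fitted rises, EEF1B2, a subunit of elongation factor 1, had 0 against 63 footprint reads. Scaled, this is 4.10 times the floor of 3 reads over the sh-NC group. The same ratio was 3.90 for PRELID3B, 3.38 for EMC7, 3.25 for NDUFB11 and PRDX4 and 1.30 for POP7 (adjusted p from 0.0165 to 0.0303). Counting error of the sh-circMYBL2 reads is left out. HIST1H4K, HIGD2A, TIMM23, HIST2H2AB and HIST1H2AK, with ratios of 1.17 or more, and HIST2H2AC, for which 14 reads leave no bound above the floor, made up the rest. RNA of HIST2H2AB (5.47 to 9.48 FPKM) and HIST1H2AK (12.3 to 15.2 FPKM) rose by more than their footprint ratios of 1.63 and 1.17. For these 2 the floor leaves no TE rise.

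Against a median TE change of 0.57 over all genes, 5 lists were called lower by camera, and none with an estimated correlation (adjusted p = 0.526 with an estimated correlation for ribosomal proteins and 0.461 for the others). That median was itself 0.23 without sh-NC footprint library 1, 1.01 without library 2, and 0.03 among genes above 0 in every library. The footprint scaling holds the last value near 0. For 28 DNA replication genes the median was -0.34 (-0.48 with 3 genes at their bounds, adjusted p = 0.0152), with MCM2 at 39.7 and 30.8 against 33.1 and 24.6 footprint RPKM. Over all genes 1 of them, PRIM1, was higher (0 against 31 reads), and adjusted over the list alone 2 were higher and 1 lower. Footprints of PRIM1 were 2.02 times the floor of 3 reads, but its RNA rose from 2.83 ± 0.535 to 5.87 ± 0.528 FPKM. The floor thus leaves no TE rise for PRIM1. The 51 histone genes had a median of -0.70 (-0.77 with 9 at their bounds, adjusted p = 0.00755) but a mean of 0.09, with 5 higher and 1 lower, or 6 and 2 adjusted over the list alone. Glycolysis genes had a median of -0.45 over 18 (adjusted p = 0.0259, none past the threshold either way), MYC and nucleolar genes 0.11 over 29 with a mean of -0.02 (adjusted p = 0.0253, none past it either way), and cytosolic ribosomal proteins 0.09 over 75 (0.04 with 1 at its bound, adjusted p = 0.0253), with RPL37A lower by either count. RPS27 was called higher by either count on 0 against 12 reads, which leave no bound above the floor.

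The 5 calls changed with single footprint libraries left out. Without sh-circMYBL2 library b none passed (adjusted p from 0.0703 to 0.258), although the medians of DNA replication (-0.36), glycolysis (-0.45) and histones (-0.70) hardly moved. Without sh-NC library 1 only DNA replication did (-0.44, adjusted p = 0.0445). There glycolysis lay at -0.0249, histones at -0.32, MYC and nucleolar genes at -0.21 and ribosomal proteins at 0.0041. Without sh-NC library 2 the DNA replication (-0.35) and MYC calls were lost and ribosomal proteins lay at -0.33. Without sh-circMYBL2 library a the MYC and ribosomal protein calls were lost and DNA replication lay at -0.67. After quantile normalization none of the 5 was called (adjusted p from 0.342 to 0.928), and ribosomal proteins (0.11) lay above the median of all genes.

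In all, 8260 genes were tested for TE by the interaction in limma, 417 higher and 22 lower, with 1618 at an unadjusted p under 0.05, and 2085 and 518 were 2-fold without overlap. That balance turned to 1009 and 1134 after quantile normalization and to 417 and 472 among genes above 0 in every library, settings that both hold the median near 0. Quantile normalization, which brought the median to 0.00, called 0 and 0 (1170 at an unadjusted p under 0.05), as did the 4186 genes above 0 in every library (721), while voom called 1 and 12. With any 1 RNA library left out 0 were called (948 to 966 at an unadjusted p under 0.05), and without sh-NC footprint library 1 or 2, or sh-circMYBL2 library a or b, there were 2186 and 934, 3723 and 1230, 744 and 102, and 657 and 81. Simulated libraries with 4-fold changes gave 4 calls of 63 among 8403 genes, with 27 false calls.

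**Figure D4:**
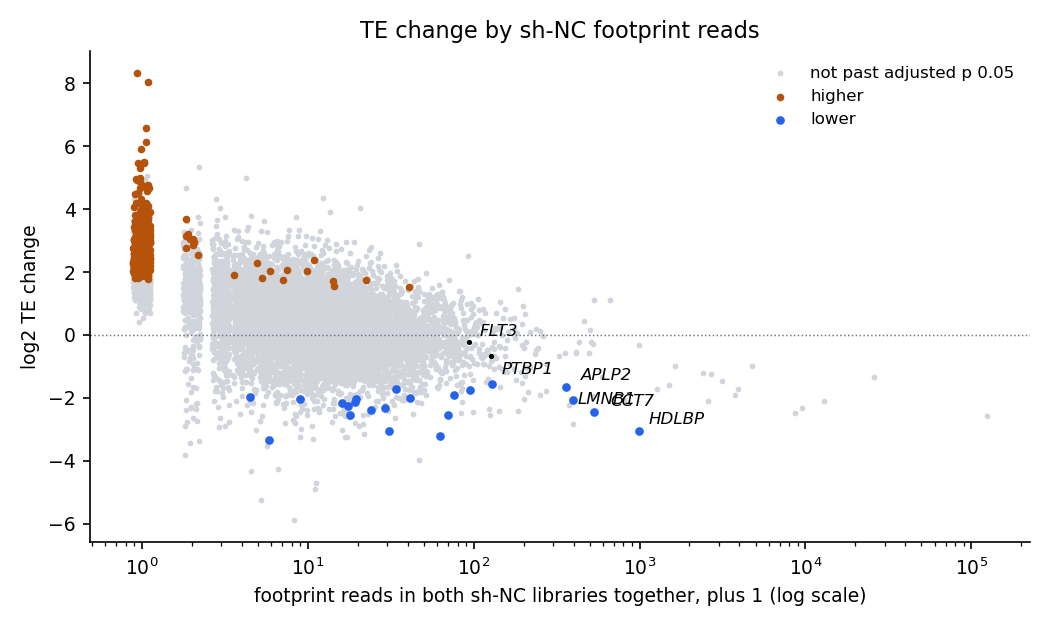
Log2 TE change (y axis) of each of 8260 genes against its footprint reads in both sh-NC libraries together plus 1 (x axis, log scale, points spread slightly sideways). The 417 higher genes lie mostly at 0 reads, where 396 of them are, and the 22 lower genes include HDLBP at 985, CCT7 at 574 and LMNB1 at 367 reads.

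Footprint changes showed little correlation with RNA changes. Across the 8260 genes in both tables, Pearson r of the log2 changes was 0.0282 and Spearman rho 0.00981, with a slope of footprint on RNA change of 0.132. With single sh-circMYBL2 and sh-NC footprint libraries set against each other r ran from 0.00572 to 0.0404, and among 988 genes with at least 50 footprint reads per library on average it was 0.0366. Footprint libraries of the same hairpin correlated with r of only 0.575 and 0.804, and such noise lowers r of the changes. How high r could be at these depths was not tested. The low r therefore does not show that translation ran apart from RNA. Genes are not independent replicates, so no p-value is given.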

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

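The tests of small RNA reads in the totals and of transcript length were chosen only after the results had been seen, and so was thinning the footprint libraries, although its bound was set earlier. The bounds of the 3 tests of the cell cycle RNAs were written before their results were seen, but the scaling test also uses the rescaling on protein-coding genes, and the swap test recovered reads, both added after the data had been seen.

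By the interaction term in limma, 417 genes were higher and 22 lower in footprints than in RNA. Of the 417, 396 had no sh-NC footprint read. No gene was called after quantile normalization (1170 at an unadjusted p under 0.05), among genes above 0 in every library (721) or with any 1 RNA library left out (948 to 966), and voom called 1 and 12. Relative to the other genes, camera called TE lower for DNA replication genes (median TE change -0.34), glycolysis genes (-0.45), MYC and nucleolar genes (0.11), cytosolic ribosomal proteins (0.0943) and histones (-0.70), each against a median of 0.57 over all genes. Fry for changes in both directions at once gave unadjusted p = 7.34e-06 for DNA replication, 2.54e-06 for histones and 0.0189 to 0.0316 for the others. This does not show that members differed either way. In TE, 3 DNA replication and 9 histone genes had no footprint read in 1 hairpin group. The variance shared with RNA may also make these p-values too small. Set against 0 by fry in a single direction, none of the 5 was called (adjusted p = 0.467, 0.221, 0.388, 0.869 and 0.388). Nor was any called with an estimated correlation (adjusted p = 0.526 for ribosomal proteins and 0.461 for the others), after quantile normalization, or without sh-circMYBL2 footprint library b.

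The shift of that median above 0 has 3 technical explanations that were tested. With the footprint libraries thinned to the same scaling total the median was still 0.452, so unequal depth at that scaling does not account for all of it. Thinning kept the deposited scaling, so any effect of depth on the scaling itself was not tested. The median was 0.63 for genes with under 20 footprint reads, 0.74 from 20 to 50, 0.41 from 200 to 500 and 0.20 for the 204 with at least 500. It was 0.03 among the 4186 genes above 0 in every library, a filter that leaves out every gene at 0 with sh-NC. That value cannot bear on the cause: the footprint scaling was set on the 4441 genes above 0 in all 4 footprint libraries. A median near 0 was largely fixed there in advance. Small RNA reads in the totals did not set the scaling: scaling total over reads on genes differed 2.52-fold between the footprint libraries, and the values follow median-ratio factors instead. In contrast, the 785 genes with the shortest exons (up to 5067 bp, at least 100 footprint reads) had a median of 0.0952 (95% interval 0.02 to 0.18) against 0.64 in the 785 longest, so uneven capture by transcript length cannot be told apart from a change in translation. The effect of the hairpin itself stays open.

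The rise of cell cycle RNAs (a median of 0.74 over 55 genes of the DNA replication and G2 and M lists) was weighed in the same way. It was not made by 1 library, since leaving out sh-NC RNA library 1 gave the lowest median, 0.719, nor by the scaling of the RNA libraries, since the median was 0.74 after quantile normalization and 0.730 after rescaling on protein-coding genes. The pseudocount did move it, to 0.43 with 5 and 0.99 with 0.1. Whether the RNA groups were swapped against the footprint groups cannot be told apart from correct labels, because RNA and footprint changes hardly followed each other (r = 0.0366 among 988 genes) in either direction. The share of mitochondrial mRNAs in protein-coding reads fell with sh-circMYBL2 in RNA (7.49% and 7.30% to 4.62% and 4.39%). In footprints it ran the same way but also fell with depth within each hairpin, so it cannot decide this. It was 0.875% and 0.626% at 33708 and 88701 protein-coding reads with sh-NC. With sh-circMYBL2 it was 0.487% and 0.255% at 125761 and 584183. Mitochondrial mRNAs are also not the genes of the pattern, and their footprint median turned to 0.23 under quantile normalization. An effect of the hairpin on the cell cycle and a difference in growth state between the cultures both stay untested.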

How the results depend on the processing

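Voom, the filter on 10 recovered reads, median-ratio scaling on protein-coding genes and thinning were chosen after seeing the data; the other alternatives were planned. FLT3 and MYBL2 RNA kept their direction in every alternative run. Lists were tested in RNA under 12 alternatives only. These were both pseudocounts, a mean of at least 5, median-ratio scaling, quantile normalization, the replicate block, each RNA library left out, an estimated correlation and fry. The 10 lists called in RNA kept their direction and call in all but 2 of these. Under the other alternatives, such as voom or all 8 libraries in 1 fit, the lists were not tested. Fry did not call glycolysis (adjusted p = 0.0714) and called hypoxia targets lower instead. The estimated correlation ended every call, but with it even histones, the strongest list, had a camera p of 0.00654 at a correlation of -0.013. Few degrees of freedom limit that setting. A pseudocount of 0.1 gave 234 and 199 2-fold genes in RNA (higher and lower), 812 and 41 TE calls and r = 0.00884 between RNA and footprint changes. A pseudocount of 5 gave 10 and 20 2-fold genes in RNA, 850 and 343 in footprints and 779 and 293 in TE, 2 and 0 TE calls (1632 at an unadjusted p under 0.05 by limma), 1 list lower in footprints and 1 higher in TE. With no filter RNA calls were 56 and 41, FLT3 RNA 0.40 (adjusted p = 0.0751) and MYBL2 RNA 1.01 (adjusted p = 0.0713), with 29835 genes tested. A mean of at least 5 gave 37 and 38 2-fold genes in RNA, 845 higher in footprints, 697 and 244 in TE, 39 and 3 TE calls, 1 list lower in footprints and 2 lower in TE. Without a trend RNA calls were 279 and 201 and FLT3 RNA 0.40 (adjusted p = 0.0608). Protein-coding genes alone gave 1407 and 1096 RNA calls, 53 and 22 2-fold genes and PTBP1 RNA 0.21 (adjusted p = 0.0299). Genes above 0 in every library gave 57 2-fold lower in RNA, 437 higher in footprints and 417 higher in TE, and 0 and 0 TE calls (721). An adjusted p under 0.1 gave 1231 and 1102 RNA and 776 and 95 TE calls. All 8 libraries in the same fit gave 0 and 0 RNA calls (91), 1100 and 190 footprint calls, and FLT3 RNA 0.40 and MYBL2 RNA 1.01 (adjusted p = 0.999952 each); this changes both the spread and the genes tested (8260). The replicate block gave 0 and 0 RNA calls (3373), FLT3 RNA 0.40 (adjusted p = 0.0545) and MYBL2 RNA 1.01 (adjusted p = 0.0727), with fewer residual degrees of freedom; numbers did not pair the RNA libraries (r = 0.0265). Voom gave 1697 and 1559 RNA, 6 and 50 footprint and 1 and 12 TE calls, PTBP1 RNA 0.22 (adjusted p = 0.000914) and MYBL2 footprints -0.24, reversed. A mean of 10 reads gave 868 and 747 RNA and 77 and 7 TE calls. Quantile normalization gave 1224 and 1429 2-fold genes in footprints and 1009 and 1134 in TE, 0 and 0 TE calls (1170), 1 list higher and 0 lower in footprints and in TE, and reversed MT-ND1 footprints (0.23), FLT3 TE (0.16) and the footprint medians of ribosomal proteins (0.19) and mitochondrial mRNAs (0.23). Thinning gave 323 and 66 TE calls, 0 lists lower in footprints and 2 in TE. The estimated correlation called 0 lists in any comparison, and fry 0 lower in footprints, and 12 higher and 0 lower in TE. Where no cause is named, the cause was not tested.

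With 1 library left out, the lone library of a group is assumed to vary like the others. Ranges were 0 to 0 for RNA calls in both directions, 133 to 150 and 121 to 142 for 2-fold genes in RNA, 0 to 742 and 0 to 4 for footprint calls, 2470 to 4311 and 648 to 1586 for 2-fold genes in footprints, 0 to 3723 and 0 to 1230 for TE calls, and 2049 to 3979 and 524 to 1263 for 2-fold genes in TE. Lists called were 5 to 6 higher and 5 to 6 lower in RNA, 0 higher and 1 to 3 lower in footprints, and 0 to 1 higher and 0 to 5 lower in TE, and r ran from 0.00570 to 0.0475. Gene changes ran from 0.35 to 0.44 (FLT3), 0.91 to 1.10 (MYBL2) and 0.12 to 0.31 (PTBP1) in RNA, from -0.0074 to 0.34, -0.71 to 0.96 and -0.59 to -0.29 in footprints, and from -0.40 to -0.06, -1.71 to -0.0455 and -0.80 to -0.51 in TE. No paired analysis was possible for footprints or TE because the footprint columns of sh-circMYBL2 name no replicate, so the replicate and culture blocks and the ratio of same-numbered libraries were not run there. Depth limits the footprints: 889 protein-coding genes had at least 10 reads in the shallowest library.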

Other observations

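Both tests of the small RNA share and all genes named in this part were chosen after their values were seen.

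Values of mitochondrial genes did not all move together. In input RNA the 12 mRNAs of the heavy strand changed by -1.66 to -0.65, while MT-ND6, the mRNA of the other strand, went from 18511 ± 337 to 21429 ± 39.2 FPKM (0.21, adjusted p = 0.208). With sh-NC this lay far above MT-ND4 (4896 FPKM). The strand setting is not given, so reads of the opposite strand may count towards MT-ND6 and the tRNAs. Its value may thus not measure its mRNA. The ribosomal RNAs changed less and did not pass by limma (MT-RNR1 -0.17, adjusted p = 0.206, and MT-RNR2 -0.30, adjusted p = 0.228). All libraries went through ribosomal RNA removal, and its effect on these 2 was not tested. Of 20 tRNAs tested, MT-TP (0.996), MT-TF (0.84) and MT-TV (0.41) rose and MT-TC (-2.40), MT-TH (-1.999), MT-TT (-1.69) and MT-TE (-0.51) fell. Calls went both ways on either strand, 1 higher and 2 lower of 8 light-strand tRNAs and 2 and 2 of 12 heavy-strand tRNAs.

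Among other genes, IL2RA, an interleukin-2 receptor chain, rose from 0.850 ± 0.0974 to 3.88 ± 0.222 FPKM (adjusted p = 0.0117), the integrin gene ITGAM from 2.84 ± 0.00409 to 5.04 ± 0.354 FPKM (adjusted p = 0.0228), and EIF4B, a translation initiation factor, from 180.3 ± 1.72 to 240.4 ± 0.148 FPKM (adjusted p = 0.0117). CTSG, a granule protease, fell from 42.1 ± 2.19 to 23.4 ± 1.86 FPKM (adjusted p = 0.0161), and EIF2S2, a subunit of eIF2, from 104 ± 4.34 to 75.8 ± 3.33 FPKM (adjusted p = 0.0237). Their lists were not called: translation factors had 1 higher and 7 lower of 45 (adjusted p = 0.686) and myeloid differentiation 3 and 3 of 20 (adjusted p = 0.127).

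MicroRNA reads per protein-coding read were 4.04 times as high in the sh-NC footprint libraries as in the others. The same ratio of small nucleolar RNA, another class of small RNA, was 3.30. Carry-over of small RNA differing between library preparations would raise both ratios. Fewer footprints with sh-NC would do so too, because both ratios divide by protein-coding reads. The 2 cannot be told apart here. Single libraries move both ratios: without sh-circMYBL2 library a they were 9.91 and 6.17, without library b 2.54 and 2.25, without sh-NC library 1 5.30 and 3.73, and without sh-NC library 2 2.78 and 2.86. In input RNA the microRNA ratio was 1.03, but microRNA genes hold few reads there, so a difference in mature microRNA between the cultures cannot be told apart. The library preparations are not described separately in the labels.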
